A study of Capsella grandiflora and Capsella rubella with 18 samples.

How the data were processed

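Messenger RNA was sequenced as paired-end Illumina libraries, per the labels' protocols, from mixed-stage flower buds of 4 C. grandiflora and 4 C. rubella plants and from leaves of 10 C. grandiflora plants, all grown in a greenhouse. The authors deposited gene expression as FPKM, a fragment count scaled to transcript length and library size, per the file headers, in 1 table with 19350 rows and 18 library columns. The submitters' processing notes name Bowtie, TopHat and Cufflinks. Their versions, the aligner parameters, how rows were chosen and how values were scaled are not given in the sources used here. Coordinates are on the CR v1 JGI build, per the file headers. Each column was assigned to a library by its name, and no column was left over.

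Bud and leaf columns differ in rounding and scale, from which separate processing is inferred; no source used here states it. The 8 bud columns are rounded to 2 decimals and their quartiles nearly coincide (medians 10.23 to 11.02 FPKM). The 10 leaf columns carry more digits, have medians of 7.2 to 10.9 FPKM and sum to about 2.5 times as much. In Cg_bud 1 and Cr_bud 1, 1023 and 1137 rows hold exactly 0.5 and only 6 and 4 hold 0, whereas the other 6 bud columns hold 0 in 1039 to 1520 rows. A step that replaced 0 by 0.5 in those 2 columns, or a further scaling of the buds, is not described in the sources used here. Since tissue and these differences coincide, no fit can tell them apart in the bud and leaf comparison. A value of 0 is reported as listed at 0. In leaf, values below 0.3 FPKM fall on read steps, with 23.9% to 27% of genes in the modal bin of the ratio to Cg_leaf 7. That ratio gives relative depths only if FPKM was scaled by read totals alone, which no source used here states. The 6 bud columns without the value 0.5 in place of 0 were examined in the same way, against Cg_bud 2, and no such steps were seen. Rounding to 2 decimals can hide steps among values this low, so their absence is not shown. The other 2 bud columns were not examined. The depth of the bud libraries and the precision it gives are therefore unknown. Of the 19350 rows, 2496 share their coordinates with another row (18078 distinct), so reads of a locus can be divided between rows and the span of a row was not used as a gene length.

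Values were analysed as log2(FPKM + 1), and a fold on this scale understates the change of low genes. A gene was tested where FPKM was at least 1 in at least 4 libraries of the fit. Groups were compared with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The species fit used the 8 bud libraries (C. rubella minus C. grandiflora) and the tissue fit 4 C. grandiflora bud and 10 leaf libraries (bud minus leaf). Tissue class came from all 8 bud against 10 leaf libraries, at an adjusted p below 0.05 and a log2 difference of at least 1. Both species thus weigh alike on the bud side, while the leaf side is C. grandiflora alone. Shares by class were compared with Fisher's exact test, libraries with exact permutation over 4 against 4, and the spread within species over all 35 splits. Binomial intervals are exact (Clopper-Pearson, 95%) and cover counting of genes only. Groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The index of both classes per library and the rank correlation with leaf were not among these tests. That rule took, per comparison and direction, the 2 genes with the largest absolute log2 difference among those with an adjusted p below 0.05, a mean of at least 5 FPKM in the higher group and no overlap between groups (3186 genes passed for species and 7821 for tissue).

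Tested on simulated data with 200 changed genes, the species fit (16923 genes) recovered 82% of changes of log2 1 and 95% of log2 2, with 14 false among 191 calls (7.33%). The tissue fit (17229 genes) recovered 49% and 90%, with 7 false among 146 calls (4.8%). The simulated noise was normal and independent between genes, and genes of low mean level were not changed. Far fewer genes were changed than were called in the real data, so these rates need not hold there.

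The 18 fixed gene lists and 16 fixed gene families could not be tested. None of the 516 symbols and loci looked up occurs in the table, which does not pair its IDs with names, and no reference table was used here. Alternatives covered the pseudocount, the filter, scaling, the trend, library weights, a fit of all 18 libraries, a fold threshold and leaving out each bud library. Alternatives added after the data were seen set 0.5 to 0, left out the 2 columns with 0.5, left out rows that share coordinates, and stratified the class test by bud abundance. One more was added on seeing that, with a bud library left out, the planned filter of 4 libraries removes genes expressed in the remaining 3 alone: the same fits with the filter asked in 3 libraries. The range of counts and the shares of directions are given under both filters. The set of genes listed at 0 in leaf was first chosen on the C. grandiflora mean and then, since that choice favours genes that are lower in C. rubella, on the mean of all 8 bud libraries. The first form held 340 genes with a median of -0.96 (log2 ratio of the group means, each with 1 added) and 176 calls, 167 of them lower in C. rubella.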

Results

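Polyadenylated RNA was sequenced from mixed-stage flower buds of 2 sister species, the self-compatible Capsella rubella (4 libraries) and the outcrossing Capsella grandiflora (4 libraries). Leaves of C. grandiflora (10 libraries) served as a reference tissue. The labels describe the plants by place of origin. Bud and leaf libraries came from different plants. The p-values of limma and of permutations of libraries measure the spread between these libraries. Those of Fisher's exact test, of binomial tests and of shuffled gene directions run across genes and leave that spread out. Expression was given as FPKM for 19350 gene rows. The FPKM values of the bud libraries summed to between 576725 and 657140 and those of the leaf libraries to between 1307609 and 1858148. Read totals were not used here. In leaf, the spacing of low values gave ratios to Cg_leaf 7 from 0.49 (Cg_leaf 9) to 1.02 (Cg_leaf 1). These are relative depths only if FPKM was scaled by read totals alone. In the 6 bud libraries examined no such spacing was seen, but rounding to 2 decimals can hide it. The depth of the bud libraries is therefore unknown. Across genes, the median correlation of log2(FPKM + 1) was 0.961 among C. grandiflora buds, 0.967 among C. rubella buds, 0.932 between the species' buds and 0.947 among leaves. It was 0.584 between C. grandiflora buds and leaves. The file does not pair its gene IDs with names, so genes are given by ID with coordinates on the CR v1 JGI build.

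The first comparison asked which genes differ in flower buds between the selfing and the outcrossing species. Differences were widespread and mostly modest. Decreases in C. rubella were more frequent among differences of at least 2-fold, and no such excess was seen at 4-fold. Of 16923 tested genes, 4053 (23.9%) differed at an adjusted p below 0.05 (limma, Benjamini-Hochberg). Of these, 2016 were higher and 2037 lower in C. rubella, with a median absolute difference of 0.69 on the log2(FPKM + 1) scale. At least 2-fold differences were found in 1108 genes, 406 of them higher and 702 lower in C. rubella (206 and 319 with a pseudocount of 5). At least 4-fold differences were found in 98 genes that were higher and 77 that were lower, so 56% were higher in C. rubella (95% exact binomial interval 48.3 to 63.5, across genes). The libraries of the 2 species did not overlap in 4750 genes (28.1%), where chance gives 2.86%. The called genes were spread over all 8 main scaffolds, with 22.1% (scaffold 6) to 26.2% (scaffold 4) of tested genes on each.

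Among the genes open to naming under the rule fixed beforehand, the largest increase in C. rubella buds was in Carubv10001442m (scaffold 6, 681486 to 683895). Its level was 84.2 ± 15.9 FPKM in C. rubella and 0.315 ± 0.25 in C. grandiflora buds (SD, n = 4 each). The difference was 6.02 on the log2 scale (SE 0.176, limma adjusted p = 9.47e-07). In C. grandiflora leaf it ranged from 0 to 26.3 FPKM and was listed at 0 in 4 of the 10 libraries. Carubv10025295m (scaffold 4, 252553 to 253987) measured 75 ± 14.5 FPKM in C. rubella and 0.835 ± 0.951 in C. grandiflora buds (SD, n = 4 each). It differed by 5.48 on the log2 scale (SE 0.325, limma adjusted p = 8.14e-05) and was listed at 0 in all 10 leaf libraries. In the other direction, Carubv10003590m (scaffold 6, 2543285 to 2548304) measured 1.32 ± 0.789 FPKM in C. rubella and 54 ± 31.1 in C. grandiflora buds (SD, n = 4 each). Its difference was -4.30 (SE 0.595, limma adjusted p = 0.00292), and its row shares its coordinates with another row, so that reads of the locus may be divided between them. Cg_bud 1 stood at 10.4 FPKM, and without it the difference was -4.95. Carubv10006368m (scaffold 7, 11412010 to 11413332) measured 7.07 ± 10.6 FPKM in C. rubella, where 1 library stood at 22.9, and 95.4 ± 42.2 in C. grandiflora buds (SD, n = 4 each). Its difference was -4.26 (SE 0.736, limma adjusted p = 0.00629), or -5.04 without that library (Cr_bud 1), and it was listed at 0 in all 10 leaf libraries.

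**Figure D1:**
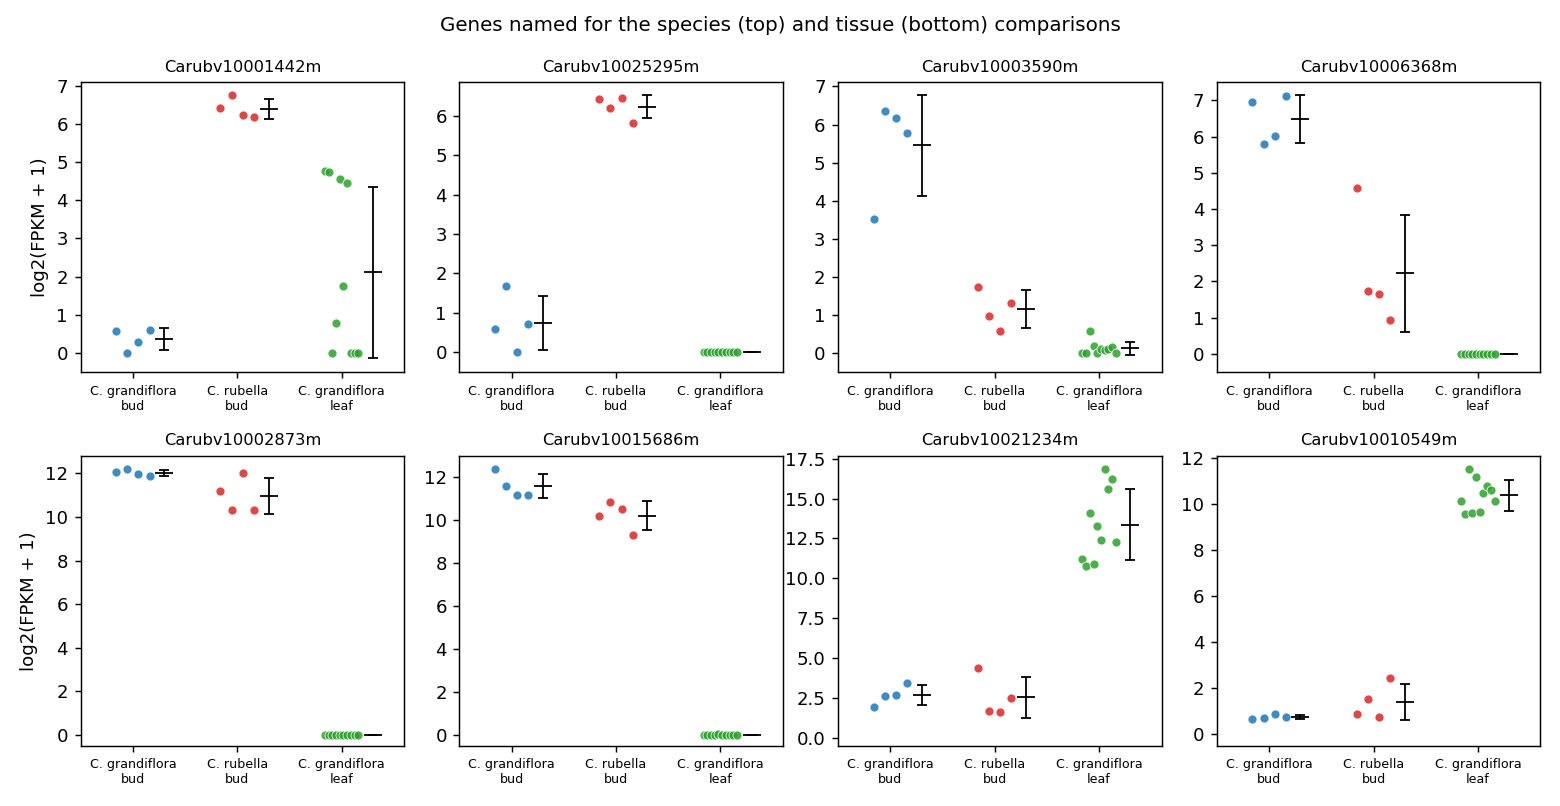
Level of the 8 named genes in each library as log2(FPKM + 1), with points for libraries and black bars for the mean and SD of C. grandiflora buds (n = 4), C. rubella buds (n = 4) and C. grandiflora leaves (n = 10). The upper row shows the genes of the species comparison, whose bud values do not overlap between species, and the lower row those of the tissue comparison, whose bud and leaf columns differ in rounding and scale.

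Few genes were near 0 in every bud library of 1 species and expressed in every bud library of the other. With near 0 set at 0.5 FPKM or below and expression at 1 FPKM or above, 29 genes were near 0 in C. grandiflora alone and 35 in C. rubella alone (exact binomial p = 0.532). With expression at 5 FPKM or above, 9 genes were near 0 in C. grandiflora alone and 1 in C. rubella alone (exact binomial p = 0.0215, two-sided, across genes). At least 1 leaf library of C. grandiflora reached 1 FPKM for 6 of those 9 genes. The size of the called set depended on the fit and the libraries. A single fit of all 18 libraries called 1500 genes, 453 higher and 1047 lower in C. rubella, and leaving out the 2 bud libraries whose columns hold 0.5 in place of 0 called 1996.

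The second comparison set C. grandiflora buds beside leaves, the reference tissue. Most tested genes differed, with changes of both directions and often of at least 4-fold. Of 17229 tested genes, 12000 (69.7%) passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 6451 higher and 5549 lower in buds. At least 2-fold differences were found in 4780 genes that were higher and 4184 that were lower in buds (2903 and 3438 with a pseudocount of 5). At least 4-fold differences were found in 2410 and 2083 genes. The libraries of the 2 tissues did not overlap in 50.7% of genes, where chance gives 0.2%. Bud and leaf columns differ in rounding and scale, so tissue cannot be told apart from a difference in processing, and the balance of directions was not stable: 53.8% of calls were higher in buds as deposited, 65.3% after upper quartile scaling and 47.2% with a filter of 5 FPKM. With quantile normalization, at least 2-fold differences numbered 4305 higher and 4754 lower in buds.

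Among the genes higher in buds, Carubv10002873m (scaffold 6, 2381124 to 2382729) measured 4180 ± 379 FPKM in C. grandiflora buds (SD, n = 4) and was listed at 0 in all 10 leaf libraries. Its level in C. rubella buds was 2280 ± 1380 FPKM (SD, n = 4). Carubv10015686m (scaffold 3, 2550840 to 2552495) measured 3170 ± 1370 FPKM in C. grandiflora buds and 1250 ± 489 in C. rubella buds (SD, n = 4 each), and it was listed at 0 in 9 of 10 leaf libraries and at 0.0289 in the other. Both passed the test between tissues, with limma adjusted p = 1.22e-18 and 1.3e-16. Among the genes higher in leaf, Carubv10021234m (scaffold 2, 12113473 to 12114011) ranged from 1730 to 121000 FPKM over the 10 leaf libraries and measured 5.85 ± 3.03 in C. grandiflora buds (SD, n = 4). Its difference was -10.70 on the log2 scale (SE 1.06, limma adjusted p = 2.23e-07). Carubv10010549m (scaffold 1, 5211632 to 5213149) measured 1480 ± 726 FPKM in leaf (SD, n = 10) and 0.693 ± 0.124 in C. grandiflora buds (SD, n = 4), a difference of -9.63 (SE 0.32, limma adjusted p = 3.47e-13). Genes restricted to 1 tissue were counted with unlike cutoffs. In all, 156 genes reached 5 FPKM in all 8 bud libraries and were listed at 0 in all 10 leaf libraries. In the other direction, 17 genes reached 5 FPKM in all leaf libraries and stood at 0.5 or below in all bud libraries. These levels come from columns that differ in rounding and scale. Leaf columns also listed 0 in more rows, from 2390 (Cg_leaf 7) to 2972 (Cg_leaf 9). The bud columns without 0.5 in place of 0 listed it in 1039 to 1520 rows. The counts of 156 and 17 are therefore not a like comparison.

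The third comparison asked whether the species difference falls on genes of buds or of leaves. Genes more abundant in buds than in leaf changed most often between the species, and those called were mainly lower in C. rubella. Called genes more abundant in leaf were mainly higher. Of 5097 tested bud-enriched genes, 1611 (31.6%) differed between species, 559 higher and 1052 lower in C. rubella. Of these, 158 were at least 2-fold higher and 543 at least 2-fold lower, so bud-enriched genes made up most of the 702 large decreases. Of 3730 leaf-enriched genes, 861 (23.1%) differed, 664 higher and 197 lower in C. rubella. Of 8096 other genes, 1581 (19.5%) differed, 793 higher and 788 lower. Over all tested genes, called or not, the balance was closer to even. The difference was above 0 in 45.8% of bud-enriched, 61.8% of leaf-enriched and 49.4% of other genes. Against the other genes, the odds of a species difference were 1.9 times as high for bud-enriched genes (95% interval 1.76 to 2.07, Fisher's exact p = 5.46e-55) and 1.24 times as high for leaf-enriched genes (1.12 to 1.36, p = 1.07e-05). These tests run across genes, which are not independent, and the tissue class rests on columns that differ in rounding and scale. Its leaf side came from C. grandiflora alone, so how C. rubella leaf would class these genes is unknown.

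**Figure D2:**
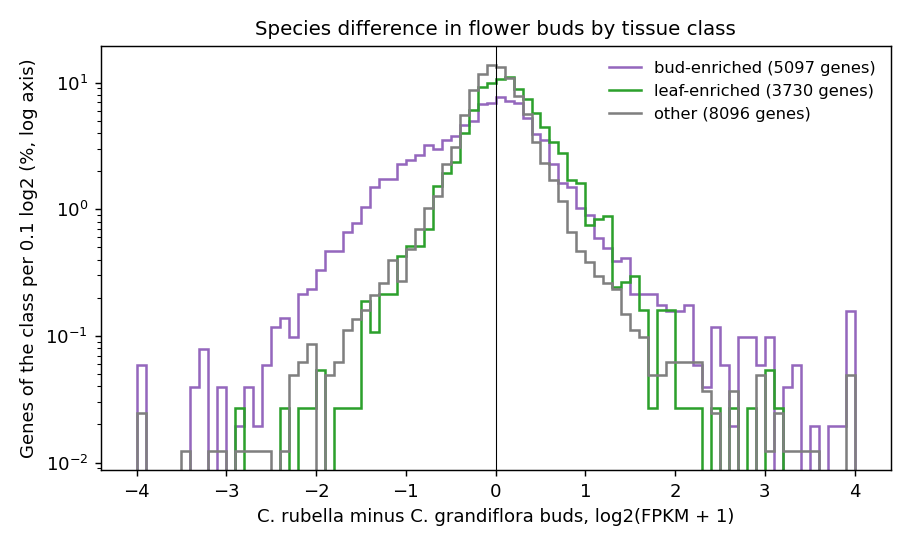
Share of genes (%, log axis) in steps of 0.1 of the log2(FPKM + 1) difference between C. rubella and C. grandiflora buds, for 5097 bud-enriched, 3730 leaf-enriched and 8096 other genes, with values beyond 4 in the outermost steps. Bud-enriched genes have the broadest left side, where 543 called genes were at least 2-fold lower in C. rubella.

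The species also differed in an index of both classes per library. The difference between the median deviation of leaf-enriched genes and that of bud-enriched genes was -0.115 ± 0.00766 in C. grandiflora and 0.0871 ± 0.0294 in C. rubella on the log2 scale (SD, n = 4 each). The index differed by 0.20 (exact permutation p = 0.0286, two-sided, the smallest p that 4 against 4 libraries allow). For bud-enriched genes alone the libraries separated by a narrow margin: the highest C. rubella median deviation was 0.0198 (Cr_bud 3) and the lowest C. grandiflora one 0.021 (Cg_bud 3). Spearman's rho of a bud library with the mean leaf profile, across genes, was 0.599 ± 0.0143 in C. grandiflora and 0.641 ± 0.00983 in C. rubella (SD, n = 4 each, exact permutation p = 0.0286, two-sided). Neither the index nor rho was among the tests fixed beforehand. Both use the same bud libraries as the class shares, so they are not separate evidence.

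Genes listed at 0 in all 10 leaf libraries, with a mean of at least 5 FPKM over the 8 bud libraries, had a lower median species difference than the bud-enriched class (-0.91 and -0.06 on the log2 scale). This set of 324 genes was chosen after the values were seen. Of its 321 tested members, 158 (49.2%) differed between species (limma, adjusted p below 0.05), 141 of them lower and 17 higher in C. rubella, and 120 were at least 2-fold lower. The quartiles of the difference over the tested members were -1.30 and 0.03. The median deviation of the set was 0.43 ± 0.26 in C. grandiflora and -0.33 ± 0.35 in C. rubella (SD, n = 4 each, exact permutation p = 0.0286, two-sided). The library Cg_bud 3 stood at 0.04, close to the highest C. rubella library at -0.07.

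**Figure D3:**
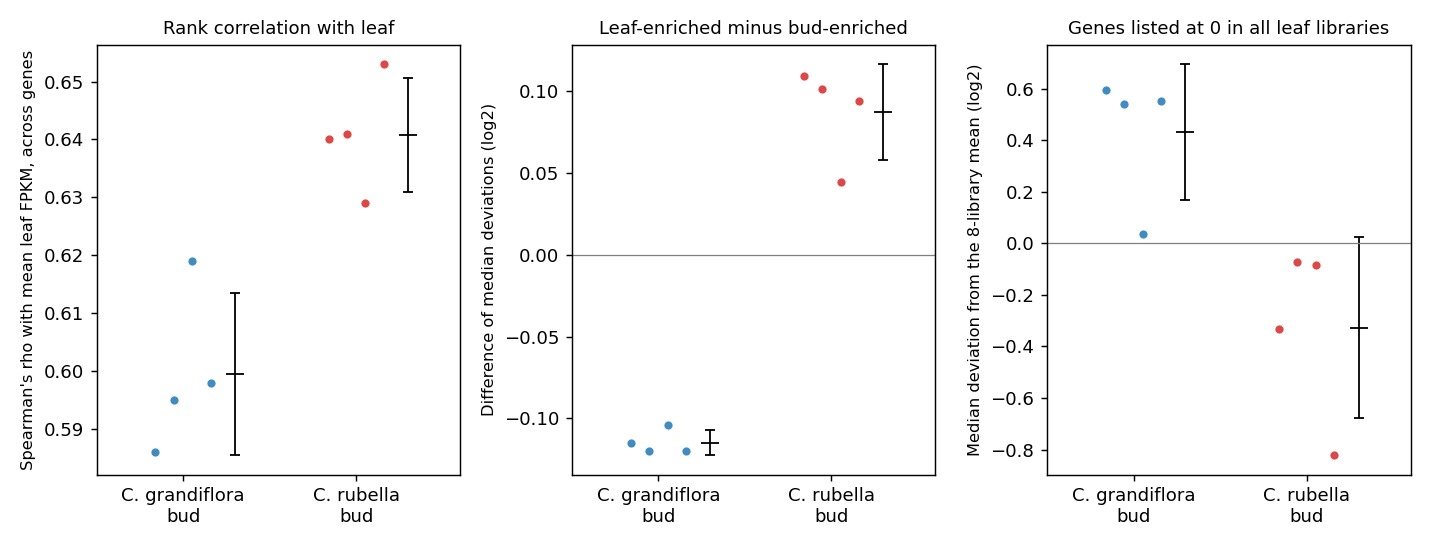
Spearman's rho with the mean leaf FPKM (left), the median deviation of leaf-enriched minus bud-enriched genes in log2 (middle) and the median deviation of genes listed at 0 in all leaf libraries in log2 (right), for 4 bud libraries per species. Points are libraries and bars the mean and SD, and in each panel all C. rubella libraries lie on 1 side of all C. grandiflora libraries.

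The fourth comparison asked whether expression varied more among plants of the outcrossing species. The median SD of log2(FPKM + 1) over the tested genes was 0.196 among the 4 C. grandiflora buds and 0.172 among the 4 C. rubella buds, and 56.1% of genes had the larger SD in C. grandiflora. After subtracting each species' mean, 14 of the 35 splits of the 8 libraries lay as far from an even share (permutation p = 0.4, two-sided), so a difference in spread was not shown. Without Cg_bud 3 the share was 45.9%, below an even share.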

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

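Values of 37 sets of libraries were searched for a library far from the rest of its group, and 7 were found, where chance gives about 1 in 20 sets. The tests of mixed leaf tissue and of scaling, the shares outside the bud-enriched class and the stage test within each species were chosen after the result was seen.

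Cg_bud 1 was listed at 0 in 6 rows against 1039 or more in the other C. grandiflora buds, and Cr_bud 1 in 4 rows against 1321 or more in the other C. rubella buds, which is where the value 0.5 stands in place of 0. The 10 most abundant genes took 3.39% of the FPKM sum in Cr_bud 2 against 4.40% or more in the other C. rubella buds. Cr_bud 1 stood apart for Carubv10006368m, at 22.9 FPKM against 2.36 or less, and for Carubv10021234m, at 19.9 FPKM against 4.66 or less. In leaf, Carubv10003590m reached 0.497 FPKM in Cg_leaf 3 against 0.13 or less, and Carubv10015686m reached 0.0289 FPKM in Cg_leaf 5 while the other leaf libraries were listed at 0.

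The species and tissue counts were set against other splits of the libraries. Of the 35 splits of the 8 bud libraries, 1, the real one, gave as many as 4053 genes, and the highest of the others gave 2. Of 100 splits of the 14 libraries, 1, the real one, gave as many as 12000 genes between tissues, and the highest of the others gave 4443. The other splits mix the groups, so a group difference widens their spread and can lower their calls. Chance is argued against as the source of both counts but not excluded, since the real split is itself 1 of 35 for the species. It does not follow that tissue rather than a difference in processing set the second.

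In C. rubella buds, most called bud-enriched genes were lower (1052 of 1611) and most called leaf-enriched genes higher (664 of 861). Leaf tissue mixed into those samples is argued against only as the source of the fall of genes listed at 0 in leaf. The mixed share, from 136 abundant leaf genes, was 0.321% (95% bootstrap interval across genes 0.126 to 0.568), or at most 1.42% after scaling for the different sums. That allows genes listed at 0 in leaf a fall of -0.02 on the log2 scale. The median log2 ratio of group means (each with 1 added) over all 324 such genes was -0.84 (interval across genes -0.94 to -0.72). Both intervals resample genes and leave out the spread between plants, and the leaf levels used are those of C. grandiflora. Whether the mixed share could give the rise of leaf-enriched genes was not tested. Scaling of the bud columns that keeps the order of genes is argued against only as the source of the difference in rank correlation with leaf. The lowest C. rubella value exceeds the highest C. grandiflora value by 0.0093, less than the SD within C. grandiflora (0.0143). The rank correlation does not test the directions of the called classes, and a scaling that reorders genes was not tested. A difference in the mix of bud stages or floral organs, which the labels leave open, was not decided. Within species, the 1052 called decreases had an SD over libraries of 0.11 against at most 0.058 in 1000 matched sets. This came from C. rubella (0.147 against at most 0.0474) and was not shown in C. grandiflora (0.0535, within its matched sets). The matched sets held uncalled bud-enriched genes that were not picked for 1 direction. Any genes regulated together could exceed them, so the SD cannot tell a mix of stages from regulation. The genes listed at 0 in leaf varied within both species, from 0.04 to 0.59 in C. grandiflora, where Cg_bud 3 was lowest, and from -0.82 to -0.07 in C. rubella, beside a species difference of -0.76, and a species difference in regulation also stays open, untested.

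Genes lower in C. grandiflora buds could reflect loss of C. grandiflora reads that differ from the C. rubella reference. Of the called genes, 49.7% were lower in C. grandiflora (95% interval 48.2 to 51.3), and of genes near 0 in 1 species alone, 45.3% were near 0 in C. grandiflora (32.8 to 58.3), so neither share decides. At 2-fold or more the share was 36.6% (33.8 to 39.6) of all called genes but 60.9% (56 to 65.7) outside the bud-enriched class, the direction of read loss, where leaf-enriched genes counted 121 against 34 and other genes 127 against 125. At 5 FPKM or more, 9 genes against 1 go in that direction too, and the 6 of the 9 that reached 1 FPKM in leaf did so in only 1 or 2 of 10 libraries and were listed at 0 in 4 to 9. Read loss therefore stays open, and no gene sequence was used here.

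Neighbouring called genes changed in 1 direction more often than shuffled directions give: 60.5% of 1073 neighbouring pairs against 47% to 52.9% in 95% of 10000 shuffles (permutation p = 1e-04, the smallest they can give). Reads shared between overlapping rows are argued against as the whole source, since 57.3% of 511 pairs at least 2000 bases apart still went together (permutation p = 5e-04). At 5000 bases or more the share was 53.9% of 282 pairs (permutation p = 0.11). Duplicated neighbours and shared regulation stay open, untested.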

How the results depend on the processing

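All 194 pairs of a named gene and an alternative in which it was tested kept its direction and its side of the threshold. These genes were picked in the same libraries for large differences without overlap, so this says little about other genes. The count of species differences (4053) moved by more than 1.5 times to 1500 in a single fit of all 18 libraries, to 1108 with a log2 difference of at least 1, and, chosen after the data were seen, to 1996 without the 2 columns with 0.5 (2343 with the filter asked in 3 libraries). For the fit of all libraries the cause was not tested; the others ask for more or use fewer libraries. With each bud library left out it ranged from 2720 to 3930 under the planned filter and from 2824 to 4089 under the filter of 3 libraries. Without Cg_bud 4 the decreases in C. rubella numbered 1281 (1396 with the filter in 3 libraries), and without Cr_bud 2 the increases numbered 1249 (1326). Increases made up 49.7% of calls as deposited, 43.2% after upper quartile scaling and 30.2% in the fit of all libraries. With a pseudocount of 5, at least 2-fold differences fell from 406 to 206 (higher) and from 702 to 319 (lower) between species, and from 4780 to 2903 (higher) between tissues, since a larger pseudocount shrinks the folds of low genes. The fit of all libraries gave 269 at least 2-fold higher and 641 lower in C. rubella, and leaving out both columns with 0.5 gave 430 lower (545 with the filter in 3 libraries). The tissue count (12000) ranged from 8964 to 13590 over its 21 alternatives. The median of all genes between tissues shifted by 0.36 with upper quartile scaling and by -0.15 with quantile normalization, and calls higher in buds were 65.3% and 50.1%. With a filter of 5 FPKM the balance turned, with 4781 higher and 5348 lower in buds (47.2%). With 1 bud library left out they were 45.7% to 46.3% under the planned filter, which then removes genes of the 3 remaining bud libraries alone, and 53.3% to 54.3% with the filter in 3 libraries. The odds ratio ranged from 1.77 to 2.26 for bud-enriched and from 1.1 to 1.51 for leaf-enriched genes (highest p = 0.0413). The share of genes with the larger SD in C. grandiflora ranged from 45.9% to 60%, and fell to 45.9%, below an even share, without Cg_bud 3; an SD of 3 libraries is also set against one of 4 there. The gene list tests and their 3 alternatives were not run, since no list member was found. No paired analysis was possible because replicate numbers only follow the order of the libraries and bud and leaf came from different plants. Unknown depth of the bud libraries limits what can be said of genes listed at 0 or 0.5.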

Other observations

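In C. grandiflora leaf, 28 genes stood at 5 FPKM or more in at least 2 libraries and at 0.1 or below in all the others. In C. rubella buds, 4 of these genes reached 5 FPKM in all 4 libraries and 1 stood at 0.5 or below in all 4. Carubv10001442m, the gene with the largest increase in C. rubella buds among the named ones, also varied among C. grandiflora leaves, from 0 to 26.3 FPKM.

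Origin of the plants was tested as a hypothesis, since Cg_bud 2 and Cg_leaf 7 share a place of origin and Cg_bud 4 and Cg_leaf 6 are crosses of plants from 1 island. Over 14585 genes, the deviations of these libraries from their group means correlated at -0.0188 and 0.177, across genes, a mean of 0.0793. Of the 90 assignments of leaf libraries to both buds, a share of 0.1 reached that mean (permutation p = 0.1, one-sided), and the highest gave 0.133. With 2 pairs, a p above the threshold excludes nothing, so this leaves the question open, although such a p had been set beforehand as counting against an effect of origin. Cg_bud 3 and Cg_leaf 4 share a number in their titles but not a place of origin, and their correlation of 0.221 was the highest of the 40. Adding this pair, after its value was seen, gave a mean of 0.127, reached by 9 of 720 assignments (permutation p = 0.0125, one-sided). Since the pair was added for its value, this p is too small. Cg_bud 4 and Cg_leaf 6 share no number in their titles, so the test does not bear on such a number alone. Cg_bud 2 and Cg_leaf 7 do share a number, and correlated at -0.0188. That expression follows the number in the title is a hypothesis only. On or off states could not be tested: only 1 of the 28 genes was also on or off among C. grandiflora buds, and its state was shared by both matched pairs (100%), as in the highest of the other assignments (100%, permutation p = 0.267).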
